A study of Homo sapiens with 15 samples.

How the data were processed

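RNA sequencing was done on total RNA that had been extracted with TRIzol from BJ fibroblasts grown in DMEM with 20% fetal bovine serum. The 15 libraries were assigned to 5 groups of 3 from the sample labels, and no column of the tables was left without a sample. The values are FPKM (fragments per kilobase of gene, scaled for the size of each library), deposited by the authors in 5 tables with gene identifiers, coordinates, lengths and biotypes. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to GRCh38 (hg38) and assigned to genes with featureCounts 1.5.0-p3. The notes do not say how the strand of reads was used, so levels of overlapping and antisense genes are uncertain, as are those of close paralogs, whose reads can be shared.

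Multiplying each FPKM by gene length and by a single factor per library gave whole fragment numbers, within a tolerance of 0.01, for 100% of the values above 0 in each library. The factor equalled the library's median-of-ratios size factor, so the deposited FPKM had been scaled by that factor and not by the library's total. The ratio of the implied scale to the assigned fragments was 0.925 ± 0.00663 in control, 0.850 ± 0.00337 and 0.973 ± 0.00760 after 4 h and 24 h of calcipotriol, 1.34 ± 0.0278 with chaetocin and 1.05 ± 0.0112 with VDR siRNA (SD, n = 3). The libraries held 15.2 to 18.3 M assigned fragments, recovered in this way.

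The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2 of FPKM with a pseudocount of 1, for genes with FPKM of at least 1 in at least 3 libraries. All 15 libraries were in 1 fit that shared an estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over the 15195 genes tested, with a threshold of 0.05. Each treated group was compared with control, as the series states, and the 24 h calcipotriol group also with the 4 h group. The test is two-sided and no covariate was used.

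Fixed gene lists, 26 in number, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes. P-values were adjusted over the lists within a comparison, and a list needed 5 tested members. Camera with the preset correlation passed 11, 11, 10, 17 and 10 of 24 lists for 4 h of calcipotriol, 24 h of calcipotriol, chaetocin, VDR siRNA and the 2 calcipotriol times. With an estimated correlation 3, 5, 1, 5 and 1 passed, and fry passed 23, 18, 22, 22 and 15. The germline and melanocyte lists, with 2 and 3 tested members, had no list test. Per gene, p-values were adjusted over all tested genes and over the list alone.

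The genes named in the text, apart from MAL among those that gained expression with chaetocin, follow a rule that was set before the data were examined. For each comparison it takes VDR, then the 8 protein-coding genes with the largest positive and the 8 with the largest negative log2 fold change among those past the threshold whose replicates do not overlap between the groups, which 10% of unchanged genes with 3 against 3 libraries would also show. From each list it takes at most 4 tested members with the smallest p, whether or not they passed, and list members at 0 where their absence is reported. Y-linked genes and XIST were left out of the tables and the text.

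Fold changes of treatments that share controls were compared by Pearson's r and covariance across genes, beside 1000 simulations of unchanged groups against shared controls. The 3 control libraries are too few to be split between the treatments.

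The main test was tested on simulated data in which 200 genes were changed, with each of 2 dispersion estimates. With the mean dispersion of 0.0175, from 78% to 84% of genes changed 2-fold and from 20% to 24% of genes changed 1.5-fold were recovered, with 2.88% to 8.77% of calls false. In 4 of 5 comparisons this did not reach the recovery of over 80% at 2-fold that had been set as a requirement. A run with the median dispersion of 0.00193 was added after that was seen, and the requirement was then limited to the recovery of whole fragments and the call of a changed list. The run with the median dispersion recovered 93% to 99% at 2-fold and 78% to 90% at 1.5-fold, with 3.89% to 8.42% of calls false. The standard error is given beside fold changes.

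Alternatives were a pseudocount of 0.1 or 0.5, no filter or a filter at FPKM 5, protein-coding genes only, TPM, median-of-ratios scaling, quantile normalization, a fit of the 6 libraries compared, robust variance estimates, array weights, a replicate block, limma-voom on the recovered fragments, an adjusted p under 0.01, a 2-fold minimum and the removal of each library in turn. The median-of-ratios scaling was computed anew on the tested genes, whereas the deposited values carry factors that equal those over all genes in the tables. Scaling by assigned fragments, and a filter of FPKM 1 in 3 libraries outside the chaetocin group, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.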

Results

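RNA from BJ cells, an established line of human foreskin fibroblasts, was sequenced in 15 libraries that fell into 5 groups of 3. The groups were control cells, cells given 100 nM calcipotriol for 4 h or for 24 h, cells given 50 nM chaetocin for 24 h, and cells given siRNA against VDR for 24 h. Calcipotriol is a synthetic vitamin D analog that binds the vitamin D receptor VDR, and chaetocin is a fungal compound described as an inhibitor of the histone methyltransferase SUV39H1. The labels do not say that control cells received vehicle or a non-targeting siRNA, nor that the 3 libraries of a group came from separate cultures, so each p-value measures only the spread between these libraries, which may be technical. The libraries held 15.2 to 18.3 M fragments assigned to genes. Group means were 17.4 ± 0.826 M in control, 16.5 ± 0.628 M at 4 h of calcipotriol, 17.0 ± 1.13 M at 24 h of calcipotriol, 15.8 ± 0.631 M with chaetocin and 16.4 ± 0.675 M with VDR siRNA (SD, n = 3). Levels below are mean FPKM ± SD over n = 3 libraries per group, and fold changes are log2 values of FPKM + 1 with their standard error. A level written against another is the treated group's mean followed by the reference group's. Genes are ranked by this log2 value, and its pseudocount of 1 holds back genes with a low level in either group. By the ratio of mean FPKM the order differs. Genes named as those that rose or fell most passed the limma threshold with no overlap between the replicates of the groups compared. Of 67653 genes in the tables, 15195 were tested, 11668 of them protein coding.

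VDR (gene ID 7421, chromosome 12, 47841537 to 47904994, minus strand on GRCh38) was lower in all 12 treated libraries than in any control library. Its level was 12.9, 10.7 and 11.3 FPKM in the 3 control libraries. It was 4.62, 3.91 and 3.86 FPKM after 4 h of calcipotriol and 8.80, 7.88 and 7.82 FPKM after 24 h. The chaetocin libraries had 2.63, 2.77 and 2.68 FPKM, and the VDR siRNA libraries had 3.53, 3.33 and 3.34 FPKM. These levels rest on 279 to 1100 fragments per library. CYP24A1 (gene ID 1591, chromosome 20, 54143538 to 54173986, minus strand), which encodes the enzyme that inactivates active vitamin D, had 0.882 ± 0.107 FPKM in control, 229 ± 8.71 FPKM after 4 h of calcipotriol and 541 ± 17.1 FPKM after 24 h. It had 1.69 ± 0.0542 FPKM with chaetocin and 0.361 ± 0.0297 FPKM with VDR siRNA, against control a log2 fold change of 0.52 ± 0.044 (adjusted p = 1.55e-07) and -0.47 ± 0.044 (adjusted p = 2.5e-06).

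**Figure D1:**
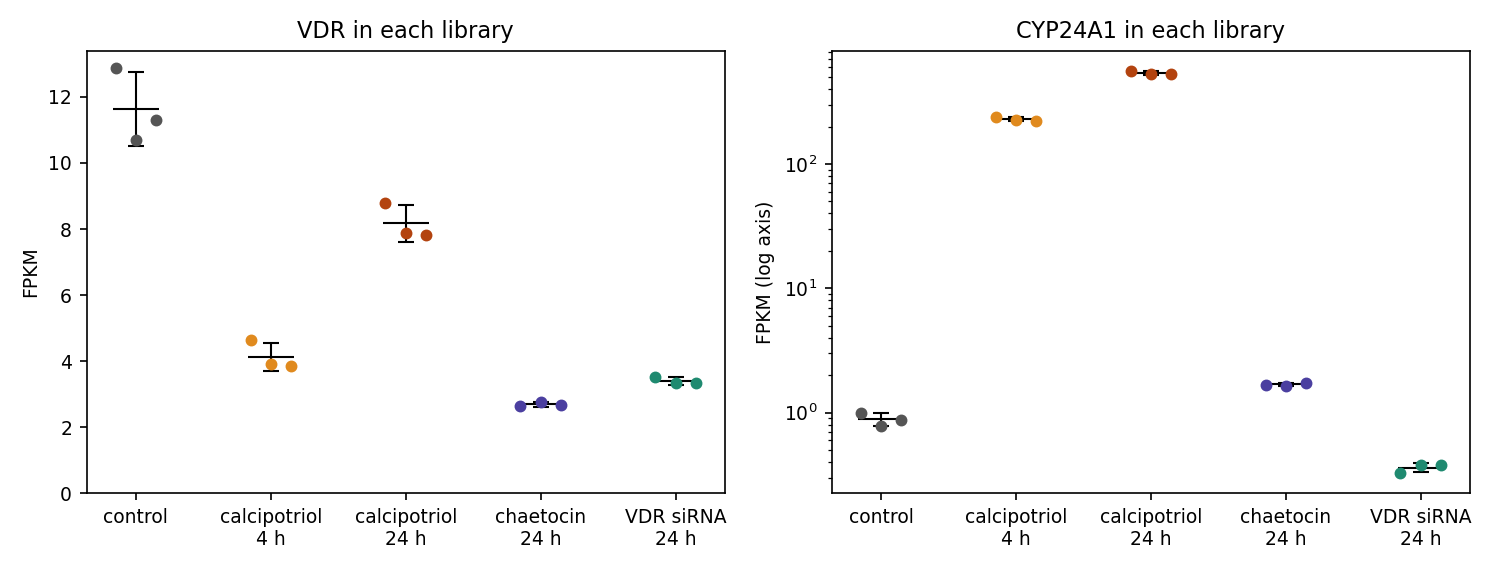
Levels of VDR (FPKM, linear axis) and CYP24A1 (FPKM, log axis) in each of the 15 libraries, with points for libraries and bars for the group mean ± SD. VDR fell from a control mean of 11.6 FPKM to between 2.69 and 8.17 FPKM in the treated groups, and CYP24A1 rose from 0.882 to 229 and 541 FPKM with calcipotriol.

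The comparison of 4 h of calcipotriol with control asks which transcripts differ soon after the receptor's ligand is added. CYP24A1 rose most (log2 fold change 6.93 ± 0.044 SE, adjusted p = 2.36e-17). THBD (gene ID 7056, chromosome 20, 23045633 to 23049672, minus strand), the anticoagulant receptor thrombomodulin, was at 109 ± 5.27 against 0.312 ± 0.0440 FPKM (log2 fold change 6.38 ± 0.053 SE, adjusted p = 3.51e-16). ID1 (gene ID 3397, chromosome 20, 31605289 to 31606510, plus strand), a target of BMP signals that inhibits transcription factors of differentiation, was at 291 ± 16.5 against 4.01 ± 0.485 FPKM. PODXL, a cell-surface sialomucin, was at 359.8 ± 8.54 against 8.01 ± 0.645 FPKM, and IL11, a cytokine of fibroblasts, was at 166 ± 3.97 against 4.12 ± 0.354 FPKM. ANKRD1, a target of YAP, ANGPTL4, an inhibitor of lipoprotein lipase, and ACTC1, the cardiac alpha actin, had log2 fold changes of 5.14 ± 0.15, 5.09 ± 0.12 and 5.08 ± 0.10. The genes that fell most were GAS1 (gene ID 2619, chromosome 9, 86944362 to 86947506, minus strand), a growth arrest gene, at 5.86 ± 0.256 against 128 ± 3.41 FPKM, and TXNIP. The latter (gene ID 10628, chromosome 1, 145992435 to 145996579, minus strand), the thioredoxin-interacting protein, was at 1.95 ± 0.117 against 39.2 ± 5.06 FPKM. The collagenase MMP1 was at 14.5 ± 1.12 against 163 ± 10.8 FPKM, and the matrix protein DPT, the glutamate transporter SLC1A3 and the alcohol dehydrogenase ADH1B had log2 fold changes of -2.91 ± 0.11, -3.03 ± 0.08 and -3.02 ± 0.098. LRRN4CL and TMEM171 fell too, with log2 fold changes of -3.44 ± 0.10 and -2.96 ± 0.10.

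Among the vitamin D target genes, 11 of 16 tested members were higher, 2 were lower and 3 did not pass (12 higher and 2 lower adjusted over the list alone). Their median was 0.91 on the log2 scale, with camera adjusted p = 0.00046 and adjusted p = 0.0225 with an estimated correlation. IGFBP3, which binds insulin-like growth factors, rose to 2659.8 ± 87.6 against 650.2 ± 10.8 FPKM, and the growth factor HBEGF rose to 55.3 ± 2.46 against 0.933 ± 0.224 FPKM. In the list of TGF-beta and myofibroblast genes, 19 of 21 tested members were higher, 0 were lower and 2 did not pass (19 higher and 0 lower adjusted over the list alone). The median there was 1.31 on the log2 scale, with camera adjusted p = 1.3e-10 and adjusted p = 0.0107 with an estimated correlation. The tropomyosin TPM1 was at 505 ± 4.65 against 95.3 ± 3.09 FPKM. Mitosis genes moved together, since 30 of 30 tested members were higher, 0 were lower and 0 did not pass (30 higher and 0 lower adjusted over the list alone). Their median was 2.17 on the log2 scale, with camera adjusted p = 4.55e-18 and adjusted p = 0.0438 with an estimated correlation. MKI67, the proliferation marker, was at 9.76 ± 0.509 against 0.876 ± 0.144 FPKM, and TOP2A, the topoisomerase of dividing cells, was at 22.4 ± 1.93 against 1.97 ± 0.326 FPKM. For DNA replication genes, 27 of 28 tested members were higher, 0 were lower and 1 did not pass (27 higher and 0 lower adjusted over the list alone). With a median of 0.82, camera gave adjusted p = 1.98e-09, and adjusted p = 0.0506 with an estimated correlation. The ribonucleotide reductase subunit RRM2 rose to 18.5 ± 0.915 against 1.82 ± 0.0565 FPKM. Every treated group is set against the same control, and few dividing cells in control alone would raise the mitosis and replication lists in each.

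Further lists passed camera with its preset correlation and not with an estimated one. They also passed fry, at adjusted p of 1.6e-10 to 0.0128. Of the interferon-stimulated genes, 0 of 25 tested members were higher, 15 were lower and 10 did not pass (0 higher and 15 lower adjusted over the list alone). A median of -0.62 had adjusted p = 0.00061, and adjusted p = 0.506 with an estimated correlation. STAT2, a transcription factor of the interferon response, was at 14.1 ± 0.400 against 48.8 ± 1.74 FPKM. Of the p53 target genes, 4 of 24 tested members were higher, 17 were lower and 3 did not pass (4 higher and 17 lower adjusted over the list alone). A median of -0.62 had adjusted p = 0.000267, and adjusted p = 0.425 with an estimated correlation. The DNA damage genes XPC and DDB2 fell to 7.98 ± 0.291 against 21.8 ± 0.488 FPKM and 6.87 ± 0.233 against 21.9 ± 0.719 FPKM, while GADD45A rose to 47.2 ± 1.63 against 13.5 ± 0.995 FPKM. Of the extracellular matrix genes, 9 of 27 tested members were higher, 17 were lower and 1 did not pass (9 higher and 17 lower adjusted over the list alone). A median of -0.30 had adjusted p = 0.0191, and adjusted p = 0.541 with an estimated correlation. The small proteoglycans DCN and LUM were at 43.5 ± 1.42 against 174 ± 11 FPKM and 133 ± 3.29 against 340.1 ± 10.9 FPKM. Of the senescence-associated secretory genes, 11 of 21 tested members were higher, 4 were lower and 6 did not pass (12 higher and 4 lower adjusted over the list alone). A median of 0.42 had adjusted p = 0.0133, and adjusted p = 0.385 with an estimated correlation. CXCL8, a chemokine that attracts neutrophils, was at 16.9 ± 0.869 FPKM and was listed at 0 in all 3 control libraries. Of the heat shock genes, 11 of 15 tested members were higher, 0 were lower and 4 did not pass (11 higher and 0 lower adjusted over the list alone). A median of 0.56 had adjusted p = 0.00127, and adjusted p = 0.42 with an estimated correlation. The chaperone HSPH1 was at 38.7 ± 1.43 against 17.8 ± 0.742 FPKM. The homologous recombination and interstrand crosslink repair genes had 15 higher and 3 lower of 21, 16 and 3 adjusted over the list alone, at adjusted p = 0.00371 and adjusted p = 0.314 with an estimated correlation. The exonuclease EXO1 was at 2.45 ± 0.298 against 0.504 ± 0.0796 FPKM. The mitochondrially encoded mRNAs had 0 higher and 6 lower of 13, 0 and 6 adjusted over the list alone. A median of -0.16 had adjusted p = 0.0384, and adjusted p = 0.634 with an estimated correlation. The NRF2 and thioredoxin genes had 8 higher and 6 lower of 21, 8 and 6 adjusted over the list alone, with adjusted p = 0.553 for the list. Of these, HMOX1, the heme oxygenase, rose to 302 ± 10.1 against 46.5 ± 2.05 FPKM and TXNRD1, the thioredoxin reductase, to 145 ± 4.37 against 46.6 ± 1.55 FPKM.

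In all, 8609 of 15195 genes passed the limma threshold after 4 h of calcipotriol, 4742 of them higher and 3867 lower, and 1181 of these changed at least 2-fold, 764 higher and 417 lower. The share that was higher was 55.1%, but 44.3% with the tables rescaled to TPM, 44.3% with each library scaled by its assigned fragments and 46.3% with quantile normalization. The repair and secretory lists did not pass at a filter of FPKM 5 (adjusted p of 7.15e-08 to 0.186 and of 3.52e-05 to 0.362 over 21 other settings), and the mitochondrial list did not pass with quantile normalization (0.0025 to 0.213) nor without control replicate 3 or calcipotriol 4 h replicate 2 or 3 (adjusted p = 0.106, 0.0608 and 0.0687), where its median was -0.050 with quantile normalization and -0.10 without control replicate 3.

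The comparison of 24 h of calcipotriol with control asks the same of the longer exposure. CYP24A1 (log2 fold change 8.17 ± 0.044 SE, adjusted p = 3.2e-18), ID1 at 283 ± 18.7 against 4.01 ± 0.485 FPKM and THBD at 30.5 ± 0.597 against 0.312 ± 0.0440 FPKM rose most. They were followed by HSPB7 (gene ID 27129, chromosome 1, 16014029 to 16019594, minus strand), a small heat shock protein of muscle, at 143 ± 9.77 against 11.4 ± 1.10 FPKM, and by SAMD11 at 45.6 ± 1.71 against 3.27 ± 0.331 FPKM. The topoisomerase TOP2A, the mitotic kinesin KIF20A and the chemokine CXCL14 had log2 fold changes of 3.39 ± 0.078, 3.31 ± 0.074 and 3.28 ± 0.15. The water channel AQP1 (gene ID 358, chromosome 7, 30911853 to 30925516, plus strand) fell most, to 1.09 ± 0.313 against 29.8 ± 1.77 FPKM (log2 fold change -3.89 ± 0.11 SE, adjusted p = 4.99e-11). ACKR4, a scavenging chemokine receptor, was at 3.33 ± 0.383 against 46.3 ± 2.18 FPKM, the signalling protein WNT5A at 4.66 ± 0.0869 against 46.5 ± 1.46 FPKM and the pentraxin PTX3 at 4.66 ± 0.441 against 42.1 ± 1.17 FPKM. FIBIN, LRRN4CL, TMEM171 and ADH1B had log2 fold changes of -3.42 ± 0.072, -3.28 ± 0.10, -2.98 ± 0.10 and -2.90 ± 0.098. VDR itself was lower than in control (log2 fold change -0.46 ± 0.072 SE, adjusted p = 0.000261).

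Of the vitamin D target genes, 13 of 16 tested members were higher, 2 were lower and 1 did not pass (13 higher and 2 lower adjusted over the list alone). Their median was 1.35 on the log2 scale, with camera adjusted p = 2.32e-11 and adjusted p = 0.000499 with an estimated correlation. The phosphatase DUSP10 rose to 33.2 ± 0.959 against 3.44 ± 0.137 FPKM. All tested mitosis genes rose, since 30 of 30 tested members were higher, 0 were lower and 0 did not pass (30 higher and 0 lower adjusted over the list alone). Their median was 2.37 on the log2 scale, with camera adjusted p = 2.44e-38 and adjusted p = 0.00506 with an estimated correlation. BIRC5, the survivin gene, was at 21.1 ± 1.88 against 2.18 ± 0.156 FPKM, and PRC1, which bundles spindle microtubules, was at 21.3 ± 1.37 against 2.71 ± 0.316 FPKM. DNA replication genes rose as well, and 22 of 28 tested members were higher, 0 were lower and 6 did not pass (23 higher and 0 lower adjusted over the list alone). Their median was 0.53 on the log2 scale, with camera adjusted p = 5.46e-11 and adjusted p = 0.0286 with an estimated correlation, and the thymidine kinase TK1 was at 29.7 ± 3.66 against 7.62 ± 0.675 FPKM. Of the homologous recombination and interstrand crosslink repair genes, 17 of 21 tested members were higher, 0 were lower and 4 did not pass (17 higher and 0 lower adjusted over the list alone). Their median was 0.40 on the log2 scale, with camera adjusted p = 2.74e-07 and adjusted p = 0.0286 with an estimated correlation. The Fanconi anemia genes FANCI and FANCD2 rose to 2.55 ± 0.136 against 0.810 ± 0.106 FPKM and 1.5 ± 0.257 against 0.292 ± 0.0615 FPKM. Cholesterol synthesis genes fell, as 0 of 22 tested members were higher, 18 were lower and 4 did not pass (0 higher and 18 lower adjusted over the list alone). Their median was -0.64 on the log2 scale, with camera adjusted p = 6.25e-12 and adjusted p = 0.0233 with an estimated correlation. DHCR7, the last enzyme of cholesterol synthesis, fell to 14.1 ± 0.324 against 26.9 ± 1.0 FPKM.

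The other lists that passed camera after 24 h did so with the preset correlation and not with an estimated one. They also passed fry, at adjusted p of 1.09e-07 to 0.00828. Of the extracellular matrix genes, 6 of 27 tested members were higher, 17 were lower and 4 did not pass (6 higher and 18 lower adjusted over the list alone). A median of -0.53 had adjusted p = 3.61e-06, and adjusted p = 0.221 with an estimated correlation. The tenascin gene TNC fell to 264 ± 10.3 against 903 ± 8.59 FPKM, whereas the crosslinking enzyme LOX rose to 482 ± 15.2 against 219.5 ± 4.83 FPKM. Of the integrated stress response genes, 12 of 17 tested members were higher, 2 were lower and 3 did not pass (12 higher and 2 lower adjusted over the list alone). A median of 0.42 had adjusted p = 3.59e-05, and adjusted p = 0.11 with an estimated correlation. The mitochondrial folate enzyme MTHFD2 was at 29.4 ± 1.89 against 16.2 ± 0.717 FPKM. The NF-kB response genes had 1 higher and 9 lower of 20, 1 and 9 adjusted over the list alone. A median of -0.16 had adjusted p = 0.00757, and adjusted p = 0.244 with an estimated correlation. The chemokine CCL2 fell to 1.36 ± 0.417 against 13.7 ± 2.75 FPKM, and NFKBIA, which encodes an inhibitor of NF-kB, rose to 18.9 ± 1.11 against 12.3 ± 1.01 FPKM. The hypoxia and glycolysis genes had 2 higher and 9 lower of 15, 3 and 11 adjusted over the list alone. A median of -0.29 had adjusted p = 0.00237, and adjusted p = 0.0874 with an estimated correlation. The glucose transporter SLC2A1 fell to 7.82 ± 0.720 against 20.7 ± 1.07 FPKM. The metallothionein genes had 4 higher and 0 lower of 6, 5 and 0 adjusted over the list alone. A median of 0.80 had adjusted p = 0.00742, and adjusted p = 0.11 with an estimated correlation. MT2A, which binds zinc and copper, rose to 769 ± 43.4 against 360.0 ± 41.0 FPKM. Of the p53 target genes, 2 of 24 tested members were higher, 11 were lower and 11 did not pass (2 higher and 11 lower adjusted over the list alone). A median of -0.21 had adjusted p = 0.0242, and adjusted p = 0.55 with an estimated correlation. The TGF-beta and myofibroblast genes had 8 higher and 7 lower of 21, 9 and 8 adjusted over the list alone (camera adjusted p = 0.388, fry adjusted p = 1.09e-07). Their median was -0.064 but their mean 0.39, and the median was above 0 with quantile normalization and with scaling by assigned fragments.

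After 24 h of calcipotriol 5062 genes passed the limma threshold, 2365 higher and 2697 lower, and 477 of these changed at least 2-fold. The share that was higher was 46.7%, but 60.9% with each library scaled by its assigned fragments, 56.0% with TPM and 55.3% among genes that changed at least 2-fold.

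Set against 4 h, the 24 h libraries show which transcripts differed between the 2 durations of calcipotriol. The labels give no control at each time, so a change in the response to calcipotriol cannot be told from time in culture. TXNIP rose most from 4 h to 24 h, to 57.9 ± 2.95 against 1.95 ± 0.117 FPKM (log2 fold change 4.32 ± 0.11 SE, adjusted p = 7.32e-12). OSR2, a transcription factor of mesenchyme, was at 33.6 ± 1.65 against 1.92 ± 0.275 FPKM, the collagen gene COL14A1 at 19.8 ± 0.557 against 1.57 ± 0.258 FPKM and the peptidase DPP4 at 97.5 ± 2.60 against 13.5 ± 0.831 FPKM. The circadian factor DBP, the chemerin gene RARRES2 and the cytochrome CYP1B1 had log2 fold changes of 2.71 ± 0.11, 2.62 ± 0.092 and 2.53 ± 0.053. MSRB1, a methionine sulfoxide reductase, had 2.72 ± 0.61, on a copy of the gene that lies on an unplaced or alternate sequence. ANGPTL4 (gene ID 51129, chromosome 19, 8364155 to 8374370, plus strand) fell most, to 3.49 ± 0.445 against 183 ± 9.0 FPKM (log2 fold change -5.36 ± 0.12 SE, adjusted p = 3.94e-12). IL11 was at 3.25 ± 0.501 against 166 ± 3.97 FPKM, HBEGF at 0.479 ± 0.0163 against 55.3 ± 2.46 FPKM and the tissue factor gene F3 at 19.4 ± 1.24 against 365 ± 10.7 FPKM. The phosphatase DUSP5, the EGFR inhibitor ERRFI1, ANKRD1 and the cyclooxygenase PTGS2 had log2 fold changes of -4.66 ± 0.063, -4.48 ± 0.081, -4.57 ± 0.15 and -4.15 ± 0.10.

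The TGF-beta and myofibroblast genes were lower at 24 h than at 4 h, as 1 of 21 tested members were higher, 19 were lower and 1 did not pass (1 higher and 19 lower adjusted over the list alone). Their median was -0.96 on the log2 scale, with camera adjusted p = 1.55e-08 and adjusted p = 0.0214 with an estimated correlation. The matricellular genes CCN1 and CCN2 were at 88.8 ± 2.96 against 539 ± 2.93 FPKM and 199.7 ± 5.60 against 1218 ± 25.7 FPKM. The remaining calls were lost with an estimated correlation. Cholesterol synthesis genes had 1 higher and 18 lower of 22, 1 and 18 adjusted over the list alone (adjusted p = 7.84e-06, and adjusted p = 0.271 with an estimated correlation). INSIG1, a sterol sensor, was at 37.6 ± 3.73 against 126 ± 1.40 FPKM. Mitosis genes had 17 higher and 0 lower of 30, 18 and 0 adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.444 with an estimated correlation). DNA replication genes had 0 higher and 19 lower of 28, 0 and 19 adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.323 with an estimated correlation). The spindle gene CENPF was at 11 ± 0.713 against 5.98 ± 0.590 FPKM, and RRM2 was at 7.99 ± 0.417 against 18.5 ± 0.915 FPKM. Heat shock genes had 0 higher and 13 lower of 15, 0 and 13 adjusted over the list alone (adjusted p = 0.000505, and adjusted p = 0.323 with an estimated correlation). The p53 target genes had 15 higher and 5 lower of 24, 15 and 5 adjusted over the list alone (adjusted p = 0.00418, and adjusted p = 0.514 with an estimated correlation). NF-kB response genes had 2 higher and 13 lower of 20, 3 and 13 adjusted over the list alone (adjusted p = 0.00541, and adjusted p = 0.323 with an estimated correlation). Senescence-associated secretory genes had 2 higher and 11 lower of 21, 2 and 11 adjusted over the list alone (adjusted p = 0.00505, and adjusted p = 0.323 with an estimated correlation). CXCL8 was at 0.0508 ± 0.0461 against 16.9 ± 0.869 FPKM. Interferon-stimulated genes had 6 higher and 0 lower of 25, 5 and 0 adjusted over the list alone (adjusted p = 0.0264, and adjusted p = 0.807 with an estimated correlation). STAT2 was at 48.2 ± 2.18 against 14.1 ± 0.400 FPKM. Hypoxia and glycolysis genes had 2 higher and 9 lower of 15, 2 and 9 adjusted over the list alone (adjusted p = 0.0264, and adjusted p = 0.323 with an estimated correlation). Vitamin D target genes had 9 higher and 6 lower of 16, 9 and 6 adjusted over the list alone (adjusted p = 0.199), with a median of 0.30 and a mean of -0.046.

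Between the 2 calcipotriol times 8271 genes passed the limma threshold, 3668 higher and 4603 lower at 24 h, and 995 of these changed at least 2-fold, 295 higher and 700 lower. The share higher at 24 h was 44.3%, 60.5% with the tables rescaled to TPM, 62.8% with scaling by assigned fragments and 54.3% with quantile normalization. The hypoxia list did not pass without calcipotriol 4 h replicate 1 (adjusted p = 0.0551), at a filter of FPKM 5, with protein-coding genes only, with quantile normalization or without genes that passed the filter through the chaetocin libraries alone (5.2e-06 to 0.156 over 21 other settings), and the interferon-stimulated list did not pass with quantile normalization or scaling by assigned fragments (0.00349 to 0.113), nor the replication, NF-kB and secretory lists at a filter of FPKM 5 (3.45e-09 to 0.0687, 1.11e-06 to 0.112 and 5.93e-07 to 0.156).

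The comparison of chaetocin with control asks which transcripts differ after 24 h with this compound. HES4 (gene ID 57801, chromosome 1, 998964 to 1000097, minus strand), a transcriptional repressor of the Notch pathway, had the largest rise by this log2 value, to 190.1 ± 4.37 against 2.01 ± 0.321 FPKM (log2 fold change 5.99 ± 0.12 SE, adjusted p = 2.06e-13). SAPCD2 was at 70.4 ± 5.37 against 0.359 ± 0.102 FPKM, CLDN6, a tight junction protein of embryonic epithelia, at 36.1 ± 1.58 against 0.0764 ± 0.0279 FPKM, and ENO3, the muscle enolase, at 124 ± 11.8 against 3.52 ± 0.0993 FPKM. The spindle genes HMMR and TACC3 had log2 fold changes of 4.61 ± 0.065 and 4.46 ± 0.053, and CYSRT1 and the Dickkopf receptor KREMEN2 had 4.45 ± 0.15 and 4.36 ± 0.11. By the ratio of mean FPKM, CLDN6 (472), SAPCD2 (196), KREMEN2 (176) and HMMR (110.3) were above HES4 (94.4). GAS1 fell most, to 1.21 ± 0.428 against 128 ± 3.41 FPKM (log2 fold change -5.88 ± 0.096 SE, adjusted p = 3.05e-14), and the matrix protein THBS1 (gene ID 7057, chromosome 15, 39581079 to 39599466, plus strand) fell to 56.4 ± 2.72 against 2099.7 ± 64.9 FPKM. PDGFRB and PDGFRA, receptors for platelet-derived growth factor, fell to 4.19 ± 0.343 against 129 ± 2.76 FPKM and 6.03 ± 0.573 against 132 ± 0.543 FPKM. CYP1B1, ACKR4, the matricellular gene CCN4 and the tight junction gene CLDN11 had log2 fold changes of -5.35 ± 0.053, -4.34 ± 0.06, -4.29 ± 0.063 and -4.03 ± 0.058. VDR had log2 fold change -1.77 ± 0.072 SE, adjusted p = 9.01e-11.

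All tested mitosis genes were higher with chaetocin, as 30 of 30 tested members were higher, 0 were lower and 0 did not pass (30 higher and 0 lower adjusted over the list alone). They had a median of 3.28, with adjusted p = 5.99e-13 and adjusted p = 0.0795 with an estimated correlation. The kinesin KIF2C was at 20.0 ± 1.06 against 1.10 ± 0.0648 FPKM. The DNA replication genes had 28 higher and 0 lower of 28, 28 and 0 adjusted over the list alone. A median of 2.35 had adjusted p = 8.56e-11, and adjusted p = 0.0674 with an estimated correlation. MCM7 and MCM2, subunits of the replicative helicase, rose to 168 ± 0.799 against 10.4 ± 0.0861 FPKM and 63.9 ± 2.03 against 4.44 ± 0.334 FPKM. The homologous recombination and interstrand crosslink repair genes had 19 higher and 1 lower of 21, 19 and 1 adjusted over the list alone. A median of 1.95 had adjusted p = 3.69e-06, and adjusted p = 0.0768 with an estimated correlation. EXO1 and the recombination gene XRCC2 rose to 10.3 ± 0.349 against 0.504 ± 0.0796 FPKM and 9.33 ± 0.374 against 0.448 ± 0.109 FPKM. Extracellular matrix genes were lower, as 0 of 27 tested members were higher, 27 were lower and 0 did not pass (0 higher and 27 lower adjusted over the list alone). They had a median of -1.89, with adjusted p = 5.99e-13 and adjusted p = 0.0795 with an estimated correlation. The fibrillin gene FBN1 fell to 20.7 ± 0.692 against 229.9 ± 2.65 FPKM and the collagen gene COL5A2 to 42.2 ± 1.47 against 213 ± 1.27 FPKM. The zinc finger ZNF genes, many of which encode repressors, were the list that held with an estimated correlation, as 231 of 401 tested members were higher, 88 were lower and 82 did not pass (231 higher and 88 lower adjusted over the list alone). Their median was 0.34 on the log2 scale, with camera adjusted p = 0.00257 and adjusted p = 0.0213 with an estimated correlation. The call was lost with quantile normalization (a median of 0.071 and adjusted p = 0.299) and with no filter (a median of 0.25 and adjusted p = 0.256), within a range of 6.63e-06 to 0.299 over the 21 other settings. ZNF367 rose to 25 ± 1.58 against 1.03 ± 0.0489 FPKM, while ZNF512B fell to 0.792 ± 0.107 against 8.21 ± 0.307 FPKM.

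Of the heterochromatin and H3K9 methylation machinery, 16 of 26 tested members were higher, 7 were lower and 3 did not pass (16 higher and 7 lower adjusted over the list alone), with adjusted p = 0.134 for the list. TRIM28, the corepressor of zinc finger proteins, rose to 651 ± 25.5 against 69.3 ± 1.71 FPKM, and the lamin gene LMNA fell to 64.7 ± 3.06 against 304 ± 8.98 FPKM. Of the heat shock genes, 11 of 15 tested members were higher, 2 were lower and 2 did not pass (11 higher and 2 lower adjusted over the list alone). A median of 1.03 had adjusted p = 0.00429, and adjusted p = 0.3 with an estimated correlation. The chaperone HSP90AA1 was at 574 ± 32.3 against 192 ± 11.7 FPKM. The NRF2 and thioredoxin genes had 13 higher and 7 lower of 21, 13 and 7 adjusted over the list alone, with adjusted p = 0.127 for the list. HMOX1 was at 799 ± 60.7 against 46.5 ± 2.05 FPKM, and TXNRD1 was at 131 ± 8.76 against 46.6 ± 1.55 FPKM. The vitamin D pathway components had 3 higher and 10 lower of 13, 3 and 10 adjusted over the list alone. A median of -0.54 had adjusted p = 0.0167, and adjusted p = 0.182 with an estimated correlation. RXRA, the partner of VDR on DNA, fell to 4.46 ± 0.215 against 17.9 ± 0.824 FPKM. The vitamin D target genes had 9 higher and 4 lower of 16, 9 and 4 adjusted over the list alone, with adjusted p = 0.127 for the list. The Wnt co-receptor LRP5 fell to 4.01 ± 0.324 against 26.9 ± 0.304 FPKM. Hypoxia and glycolysis genes had 2 higher and 12 lower of 15, 2 and 12 adjusted over the list alone. A median of -0.60 had adjusted p = 0.0106, and adjusted p = 0.151 with an estimated correlation. The vasodilator peptide gene ADM fell to 32.7 ± 1.82 against 262 ± 18.1 FPKM. The leukocyte markers had 5 higher and 0 lower of 6, 5 and 0 adjusted over the list alone. A median of 1.61 had adjusted p = 0.0118, and adjusted p = 0.242 with an estimated correlation. Of these markers 1 had a mean of at least 1 FPKM in control and 6 had with chaetocin, so most entered the test through the chaetocin libraries, and their number higher follows in part from the filter. The scavenger receptor CD163, for example, was at 3.28 ± 0.315 against 0.0463 ± 0.010 FPKM. Ribosomal protein genes had 8 higher and 41 lower of 75, 8 and 37 adjusted over the list alone. A median of -0.19 had adjusted p = 0.0112, and adjusted p = 0.684 with an estimated correlation. The median turned positive with TPM (0.05), with scaling by assigned fragments (0.33) and with quantile normalization (0.10). The list passed with none of these 3, nor at a filter of FPKM 5, with protein-coding genes only, with median-of-ratios scaling or without genes that passed the filter through the chaetocin libraries alone (adjusted p of 4.27e-10 to 0.377 over 21 other settings). Integrated stress response genes had 8 higher and 8 lower of 17, 9 and 8 adjusted over the list alone (adjusted p = 0.943). The phosphatase subunit PPP1R15A rose to 217 ± 22.6 against 15.3 ± 1.52 FPKM, and the chaperone HSPA5 fell to 46.9 ± 3.01 against 179 ± 5.78 FPKM.

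More genes were detected with chaetocin than in any other group. At least 1 fragment was assigned to 36313 ± 236 genes with chaetocin, against 23486 ± 156 in control, 22106 ± 258 and 24109 ± 364 with calcipotriol for 4 h and 24 h, and 24016 ± 143 with VDR siRNA (SD, n = 3). The 10 most abundant genes took 10.8 ± 0.382% of the fragments with chaetocin, 12.5 ± 0.446% with VDR siRNA, 14.8 ± 0.141% and 17.7 ± 0.189% after 4 h and 24 h of calcipotriol and 17.8 ± 0.136% in control. Mitochondrial genes took 6.84 ± 0.455% with chaetocin, 4.84 ± 0.113% with VDR siRNA, 3.86 ± 0.0710% and 4.801 ± 0.112% with calcipotriol and 4.63 ± 0.290% in control. The chaetocin libraries stood apart on the first principal component, at 97.2 to 100.2 against -30.9 to -18.4 for the other 12. With chaetocin 12026 genes passed the limma threshold, 6221 higher and 5805 lower, and 4905 of these changed at least 2-fold, 3110 higher and 1795 lower. Scaling each library by its assigned fragments moved the median log2 fold change of all genes from 0.028 to 0.44, and TPM moved it to 0.25, so that the share higher went from 51.7% to 72.4% with scaling by assigned fragments and 61.5% with TPM, but it was 38.3% at a filter of FPKM 5 (2683 higher and 4321 lower), 43.7% with protein-coding genes only, 47.8% with quantile normalization, 75.6% with no filter (19309 and 6219) and 40.2% without genes that passed the filter through the chaetocin libraries alone. The hypoxia list did not pass at a filter of FPKM 5 or with quantile normalization (adjusted p of 1.27e-05 to 0.101 over 21 other settings), nor did the vitamin D pathway list with protein-coding genes only (3.12e-05 to 0.0529).

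**Figure D2:**
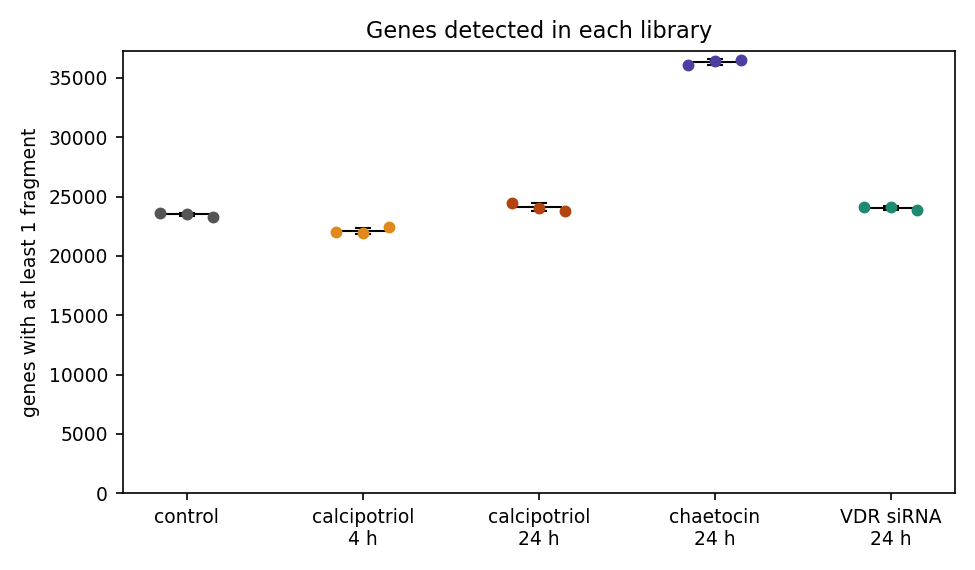
Number of genes with at least 1 fragment (linear axis from 0) in each of the 15 libraries, with points for libraries and bars for the group mean ± SD. The chaetocin libraries had 36044 to 36483 genes and the other 12 libraries had 21924 to 24493.

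The comparison of VDR siRNA with control asks which transcripts differ in cells given this siRNA. VDR mRNA was lower than in control in the other treated groups too, so its fall is not particular to the siRNA. The labels name no non-targeting siRNA. An effect of reduced VDR therefore cannot be told from a response to transfection or to siRNA itself. VDR was at 3.40 ± 0.112 against 11.6 ± 1.13 FPKM (log2 fold change -1.52 ± 0.072 SE, adjusted p = 3.8e-09). ID1 rose most, to 54.3 ± 4.12 against 4.01 ± 0.485 FPKM (log2 fold change 3.46 ± 0.08 SE, adjusted p = 6.37e-12). It was followed by CDC20 (gene ID 991, chromosome 1, 43358981 to 43363203, plus strand), an activator of the anaphase ubiquitin ligase, at 30.9 ± 1.89 against 2.14 ± 0.732 FPKM. KIF20A was at 21.4 ± 0.455 against 1.25 ± 0.229 FPKM and the cyclin gene CCNB1 at 36.6 ± 3.06 against 3.41 ± 0.474 FPKM. TOP2A, BIRC5, PODXL and the ubiquitin-conjugating enzyme UBE2C had log2 fold changes of 3.21 ± 0.078, 3.13 ± 0.056, 3.20 ± 0.06 and 3.06 ± 0.13. AQP1 fell most, to 2.47 ± 0.223 against 29.8 ± 1.77 FPKM (log2 fold change -3.15 ± 0.11 SE, adjusted p = 3.07e-10). PSAT1 (gene ID 29968, chromosome 9, 78297125 to 78330093, plus strand), an enzyme of serine synthesis, fell to 8.76 ± 0.678 against 73.0 ± 2.91 FPKM, the microfibril protein MFAP4 to 35.1 ± 0.958 against 209.5 ± 9.17 FPKM and CCN4 to 3.40 ± 0.15 against 29.8 ± 0.739 FPKM. ADH1B, the Wnt antagonist DKK2, LRRN4CL and the growth factor PDGFD had log2 fold changes of -2.97 ± 0.098, -2.85 ± 0.12, -2.71 ± 0.10 and -2.50 ± 0.10.

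With VDR siRNA 30 of 30 tested members were higher, 0 were lower and 0 did not pass (30 higher and 0 lower adjusted over the list alone) among the mitosis genes. Their median was 2.59 on the log2 scale, with camera adjusted p = 1.06e-34 and adjusted p = 0.00944 with an estimated correlation. For DNA replication genes the counts were 27 higher and 0 lower of 28, 27 and 0 adjusted over the list alone. Their median was 1.11 on the log2 scale, with camera adjusted p = 3.57e-19 and adjusted p = 0.00944 with an estimated correlation, and the helicase subunit MCM4 was at 26.2 ± 0.912 against 9.31 ± 0.356 FPKM. The homologous recombination and interstrand crosslink repair genes had 15 higher and 0 lower of 21, 16 and 0 adjusted over the list alone. Their median was 0.51 on the log2 scale, with camera adjusted p = 1.23e-06 and adjusted p = 0.0399 with an estimated correlation. The recombination helicase RAD54L was at 2.69 ± 0.352 against 0.460 ± 0.120 FPKM. All tested extracellular matrix genes fell, as 0 of 27 tested members were higher, 27 were lower and 0 did not pass (0 higher and 27 lower adjusted over the list alone). Their median was -0.85 on the log2 scale, with camera adjusted p = 5.67e-26 and adjusted p = 0.0175 with an estimated correlation. COL1A1, the main collagen chain of skin, fell to 2042 ± 75.4 against 5562 ± 58.9 FPKM and LUM to 91.9 ± 2.04 against 340.1 ± 10.9 FPKM. Most vitamin D target genes that passed were higher, since 11 of 16 tested members were higher, 2 were lower and 3 did not pass (11 higher and 2 lower adjusted over the list alone). Their median was 0.42 on the log2 scale, with camera adjusted p = 0.00209 and adjusted p = 0.0348 with an estimated correlation. THBD was at 3.53 ± 0.292 against 0.312 ± 0.0440 FPKM, IGFBP3 at 1674 ± 31.2 against 650.2 ± 10.8 FPKM and SPP1, the osteopontin gene, at 12.5 ± 0.873 against 3.05 ± 0.697 FPKM. CYP24A1 fell, as did LRP5, to 14.2 ± 0.0814 against 26.9 ± 0.304 FPKM. The vitamin D pathway components had 1 higher and 5 lower of 13, 1 and 7 adjusted over the list alone. A median of -0.13 had adjusted p = 0.00644, and adjusted p = 0.0987 with an estimated correlation.

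**Figure D3:**
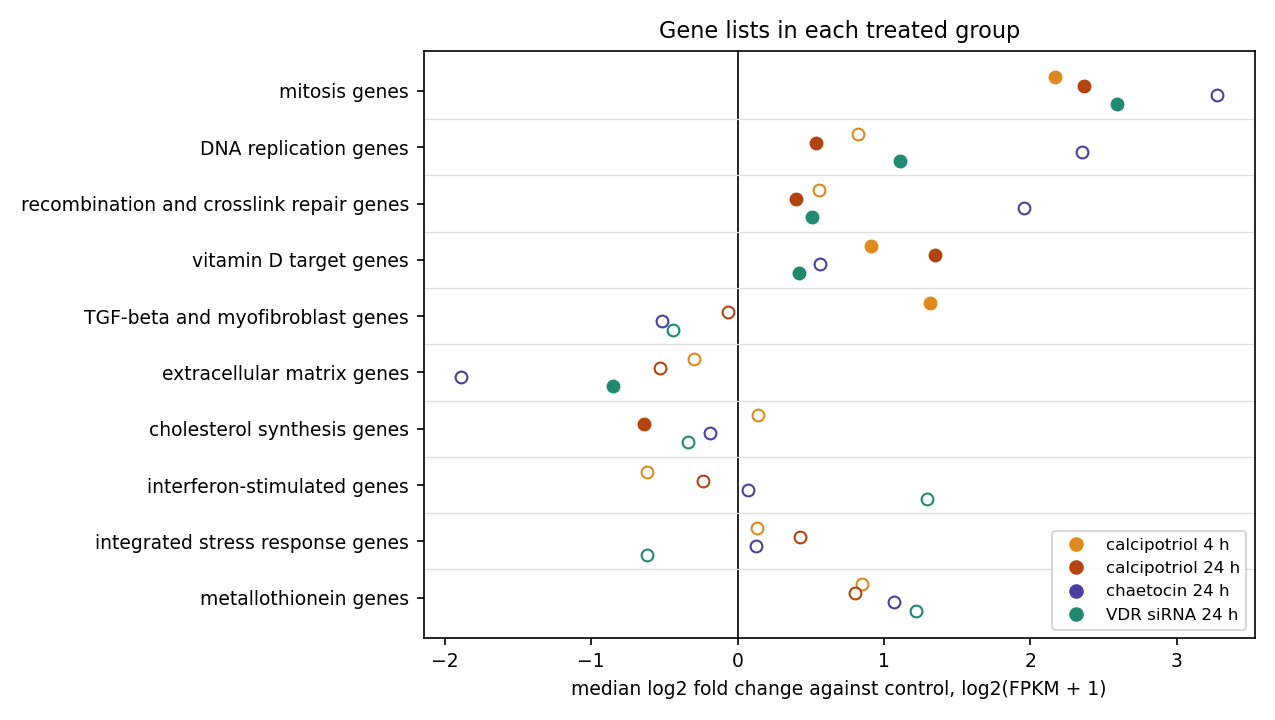
Median log2 fold change against control of 10 gene lists in the 4 comparisons with control, with filled points where the adjusted p was under 0.05 in camera with an estimated correlation and open points where it was not. For 4 h and 24 h of calcipotriol, chaetocin and VDR siRNA the mitosis list had medians of 2.17, 2.37, 3.28 and 2.59, and the extracellular matrix list had -0.30, -0.53, -1.89 and -0.85.

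Interferon-stimulated genes were higher with VDR siRNA, as 24 of 25 tested members were higher, 0 were lower and 1 did not pass (24 higher and 0 lower adjusted over the list alone). A median of 1.29 had adjusted p = 1.75e-11, and adjusted p = 0.127 with an estimated correlation. The antiviral genes MX1, OAS2 and OAS3 were at 42.4 ± 17.6 against 4.82 ± 0.502 FPKM, 12.9 ± 5.24 against 1.22 ± 0.232 FPKM and 19.4 ± 6.37 against 2.84 ± 0.137 FPKM, with a wide spread between the siRNA libraries. The NF-kB response genes had 13 higher and 0 lower of 20, 13 and 1 adjusted over the list alone. A median of 0.46 had adjusted p = 9.35e-05, and adjusted p = 0.0922 with an estimated correlation. The superoxide dismutase gene SOD2 rose to 20.7 ± 4.15 against 6.91 ± 0.0817 FPKM, and CXCL8 was at 1.78 ± 0.527 FPKM, listed at 0 in control. Of the p53 target genes, 14 of 24 tested members were higher, 4 were lower and 6 did not pass (14 higher and 4 lower adjusted over the list alone). A median of 0.24 had adjusted p = 0.00644, and adjusted p = 0.371 with an estimated correlation. The stress cytokine GDF15, which the secretory list holds too, rose to 79.4 ± 2.77 against 14.9 ± 1.20 FPKM. The senescence-associated secretory genes had 13 higher and 5 lower of 21, 13 and 5 adjusted over the list alone. A median of 0.45 had adjusted p = 0.027, and adjusted p = 0.235 with an estimated correlation. The stromelysin MMP3 rose to 402 ± 8.99 against 152 ± 3.53 FPKM. TGF-beta and myofibroblast genes had 5 higher and 15 lower of 21, 5 and 15 adjusted over the list alone. A median of -0.44 had adjusted p = 0.000762, and adjusted p = 0.0672 with an estimated correlation. The smooth muscle actin ACTA2 fell to 52.4 ± 1.52 against 165 ± 3.36 FPKM. Integrated stress response genes had 2 higher and 11 lower of 17, 2 and 11 adjusted over the list alone. A median of -0.62 had adjusted p = 5.64e-05, and adjusted p = 0.0987 with an estimated correlation. PHGDH, the entry enzyme of serine synthesis, fell to 7.02 ± 0.419 against 29.3 ± 2.16 FPKM.

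With VDR siRNA cholesterol synthesis genes had 0 higher and 17 lower of 22, 0 and 17 adjusted over the list alone (adjusted p = 1.23e-06, and adjusted p = 0.0672 with an estimated correlation). Metallothionein genes had 5 higher and 0 lower of 6, 5 and 0 adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.0672 with an estimated correlation), MT2A being at 1295 ± 111 against 360.0 ± 41.0 FPKM. Heat shock genes had 12 higher and 0 lower of 15, 13 and 1 adjusted over the list alone (adjusted p = 0.000268, and adjusted p = 0.166 with an estimated correlation). Hypoxia and glycolysis genes had 2 higher and 7 lower of 15, 2 and 7 adjusted over the list alone (adjusted p = 0.0085, and adjusted p = 0.0987 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, fell to 49.8 ± 0.635 against 111 ± 1.5 FPKM. Ribosomal protein genes had 3 higher and 37 lower of 75, 3 and 37 adjusted over the list alone (adjusted p = 1.72e-05, and adjusted p = 0.392 with an estimated correlation). Their median of -0.16 was above 0 with scaling by assigned fragments. With VDR siRNA 5714 genes passed the limma threshold, 2885 higher and 2829 lower, and 582 of these changed at least 2-fold, 336 higher and 246 lower. The share higher was 50.49%, 49.0% with quantile normalization, 49.4% with median-of-ratios scaling, 66.7% with the tables rescaled to TPM and 77.3% with scaling by assigned fragments, which moved the median of all genes from 0 to 0.11. The secretory list did not pass with that scaling, at a filter of FPKM 5 or without genes that passed the filter through the chaetocin libraries alone (adjusted p of 4.67e-05 to 0.356 over the 21 other settings).

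Treatments that share the control libraries were compared through their fold changes across the 15195 genes, which are not independent replicates. For 24 h of calcipotriol and VDR siRNA, Pearson's r was 0.599, against 0.501 (a central range of 0.459 to 0.544 over 1000 simulations) for unchanged groups set against shared controls. The covariance was 0.116, against 0.0157 simulated. Both treatments raised 1346 genes, where 449 would be shared if calls were independent, and both lowered 1529, where 502 would be. Opposite directions were found for 213 and 249 genes, where 440.3 and 512 would be. Independence leaves out the shared controls, here and for the pairs below. Unchanged groups set against shared controls gave 0 genes called in the same direction in each of 50 simulations. With no gene changed, hardly any gene can pass in either comparison. These simulations therefore do not show how far shared controls raise the numbers of shared calls. The mitosis gene KIF20A had 3.31 ± 0.074 and 3.32 ± 0.074, and AQP1 had -3.89 ± 0.11 and -3.15 ± 0.11, while PSAT1 had 0.38 ± 0.055 with calcipotriol and -2.92 ± 0.055 with VDR siRNA. Tested directly against each other, VDR siRNA and 24 h of calcipotriol differed in 4976 genes, 2794 of them higher with VDR siRNA. In that test vitamin D target genes had 2 higher and 12 lower of 16, 2 and 12 adjusted over the list alone (adjusted p = 3.94e-09, and adjusted p = 0.00154 with an estimated correlation). The TGF-beta and myofibroblast genes had 3 higher and 15 lower of 21, 3 and 16 adjusted over the list alone (adjusted p = 5.7e-09, and adjusted p = 0.0127 with an estimated correlation), and the integrated stress response genes had 1 higher and 14 lower of 17, 1 and 14 adjusted over the list alone (adjusted p = 2.42e-11, and adjusted p = 0.0214 with an estimated correlation). The DNA replication genes had 23 higher and 0 lower of 28, 25 and 0 adjusted over the list alone (adjusted p = 1.29e-11, and adjusted p = 0.0214 with an estimated correlation), and the NF-kB response genes had 19 higher and 0 lower of 20, 19 and 1 adjusted over the list alone (adjusted p = 1.46e-10, and adjusted p = 0.0214 with an estimated correlation). The zinc finger ZNF genes had 16 higher and 42 lower of 401, 12 and 24 adjusted over the list alone (adjusted p = 0.0336, and adjusted p = 0.0418 with an estimated correlation). The interferon-stimulated genes had 24 higher and 0 lower of 25, 24 and 0 adjusted over the list alone (adjusted p = 1.82e-14, and adjusted p = 0.121 with an estimated correlation). Further lists passed camera with the preset correlation and not with an estimated one.

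For 4 h and 24 h of calcipotriol r was 0.462 and the covariance 0.124, and both times raised 1394 genes (738 if independent) and lowered 1345 (686). ID1, THBD and CYP24A1 were among the genes named as those that rose most at both times. Other named genes, TOP2A among them, rose at both times too. For chaetocin and 24 h of calcipotriol r was 0.363 and the covariance 0.171, with 1272 genes raised by both (968 if independent) and 1948 lowered by both (1030). For chaetocin and VDR siRNA r was 0.396 and the covariance 0.191, with 1491 genes raised by both (1181 if independent) and 2046 lowered by both (1081). ACKR4 fell in both 24 h compound groups, and CCN4 fell with chaetocin and with VDR siRNA. The r of 0.462 lay within the central range simulated for shared controls and the values with chaetocin lay below it, whereas each of these covariances was above the simulated 0.0157. The simulated r is that of groups with no change, and the observed r also depends on the size of each treatment's effects. Its place against that range thus does not show how alike the effects were. Chaetocin differed from 24 h of calcipotriol in 11961 genes and from VDR siRNA in 11872 genes when tested directly.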

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

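The genes and lists below differed from control, past the threshold, after 4 h or 24 h of calcipotriol, and also differed between the 2 times when these were tested directly. Genes were tested with limma and lists with camera at the preset correlation. The labels give no control at each time, so a change in the effect of calcipotriol cannot be told from time in culture. Values are log2 differences, 24 h minus 4 h, over n = 3 libraries per time. No explanation of them was tested and no test was chosen after the result was seen.

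Of all genes tested, 8271 differed between the times. TXNIP was higher at 24 h by 4.32, CXCL14 by 2.41, SLC1A3 by 2.06, DPT by 1.75, GAS1 by 1.59 and MMP1 by 1.30. All but CXCL14 of these were lower than control at 4 h, and CXCL14 was among the genes that rose most by 24 h. CYP24A1 gained a further 1.24 and VDR recovered by 0.84, while the mitosis genes KIF20A and TOP2A gained 0.77 and 0.41.

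HSPB7 differed by -0.67, SAMD11 by -0.75, FIBIN by -0.79, ACKR4 by -0.94, WNT5A by -1.40, AQP1 by -1.62 and PTX3 by -1.63. Of the genes induced at 4 h, THBD differed by -1.80, ACTC1 by -1.96, PODXL by -2.09, ANKRD1 by -4.57, IL11 by -5.31 and ANGPTL4 by -5.36.

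Among the lists, the medians of the difference were 0.55 for p53 target genes, 0.29 for interferon-stimulated genes and 0.27 for mitosis genes. They were -0.20 for senescence-associated secretory genes, -0.37 for DNA replication genes, -0.38 for NF-kB response genes, -0.41 for hypoxia and glycolysis genes, -0.43 for heat shock genes, -0.69 for cholesterol synthesis genes and -0.96 for TGF-beta and myofibroblast genes. Of these lists, TGF-beta and myofibroblast genes alone passed camera with an estimated correlation (adjusted p = 0.0214).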

How the results depend on the processing

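Scaling by assigned fragments and the filter outside the chaetocin group were chosen after the results were seen, and the other settings before. The counts of genes past the threshold stayed within 1.5 times the main count, except where the rule itself took fewer or more genes. With a 2-fold minimum they were 1181 for 4 h of calcipotriol, 477 for 24 h, 4905 for chaetocin, 582 for VDR siRNA and 995 between the times, and for chaetocin 25528 with no filter and 7004 at FPKM 5. With FPKM of at least 1 required in 3 libraries outside the chaetocin group, 12700 genes were tested and the counts were 8201, 4977, 9635, 5611 and 7934. This filter ended the calls of the ribosomal list with chaetocin, the secretory list with VDR siRNA and the hypoxia list between the times, and gave 5 with chaetocin, for vitamin D target (adjusted p = 0.0337), heterochromatin (0.0267), NF-kB (0.0267), NRF2 (0.0199) and metallothionein genes (0.0337). The correlations of chaetocin with 24 h of calcipotriol and with VDR siRNA were 0.427 and 0.476 there. With a library left out they were 8012 to 8626, 4454 to 5097, 11664 to 12028, 5045 to 5711 and 7678 to 8280. With the replicate number as a block they were 8575, 4997, 12006, 5626 and 8217, and the numbers do not pair the libraries, since 0 of 30 pairs with the same number correlated above 0.1. Limma-voom gave 8544, 5177, 12113, 5834 and 8240. Of 555 results for named genes, 514 were past the threshold, and of 120 list results 59 were. With a library left out, 3283 named-gene results kept their side of the threshold, 34 lost it and 13 gained it, and 711 list results kept it, 4 lost it and 5 gained it. No filter ended 1 list call and gave 23, and quantile normalization ended 5, gave 7 and turned 2. The FPKM 5 filter ended 9 list calls and gave 4, and some lists and named genes had no value there, since they or their members fell under it. The correlation of 24 h of calcipotriol with VDR siRNA, of 24 h of calcipotriol with chaetocin and of VDR siRNA with chaetocin was 0.573, 0.327 and 0.352 at a pseudocount of 0.1, and 0.620, 0.417 and 0.463 with protein-coding genes only. The 2 correlations with chaetocin were 0.351 and 0.379 at a pseudocount of 0.5, 0.349 and 0.380 with no filter, 0.330 and 0.344 with TPM, 0.339 and 0.340 with scaling by assigned fragments, and 0.330 and 0.347 with limma-voom. At FPKM 5 the correlations were 0.486 for the 2 calcipotriol times, then 0.633, 0.413 and 0.468, and with quantile normalization that of the 2 times was 0.480 and that of 24 h of calcipotriol with chaetocin 0.343. With a library left out they were 0.439 to 0.483, 0.574 to 0.618, 0.351 to 0.375 and 0.383 to 0.406. Signs of fold changes, and of medians for lists, turned with TPM for CYTB with chaetocin (0.031) and for ribosomal protein genes with chaetocin (0.046) and between the times (0.11). They turned with scaling by assigned fragments for CYTB with chaetocin (0.32) and for ribosomal protein genes with chaetocin (0.33), with VDR siRNA (0.016) and between the times (0.13). With quantile normalization they turned for CYTB at 24 h of calcipotriol (0.095), with chaetocin (0.58) and with VDR siRNA (0.069), for ND3 at 24 h (0.039) and with VDR siRNA (0.059), for CD68 at 4 h (-0.13), FLT1 with chaetocin (-0.42) and DSP between the times (0.051), and for ribosomal protein genes with chaetocin (0.10) and between the times (0.21). The sign of a median moves with a shift of all genes. Camera's direction, which is set against other genes, turned for 1 list result with TPM and 2 with scaling by assigned fragments. The cause was not tested. Depth was 15.2 to 18.3 M fragments, and genes that reached FPKM 1 in fewer than 3 libraries were not tested.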

Other observations

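The tests of library scaling, of few dividing cells in control and of chance values in shared controls were chosen after the result was seen, as were the bound from olfactory receptor genes, the comparison with a single rate, the distances of genes without a fragment in control and the simulated share of signs. The other tests were set before.

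With chaetocin the balance of long noncoding RNA genes depended on the filter. Of 1604 tested 1175 were higher and 190 lower, many of which entered through the chaetocin libraries, and of the 710 that passed the filter outside the chaetocin group 305 were higher and 190 lower, while of the 404 with at least 1 FPKM in each control library, a level that leaves out genes that rose from below it, 132 were higher and 163 lower. After 4 h of calcipotriol 43 of 245 small nucleolar RNA genes were higher and 4 were lower, 18 and 3 of the 72 at that level in control, and 175 long noncoding RNA genes were higher and 332 lower, 53 and 196 of those 404. With chaetocin 613 genes reached at least 1 FPKM that were under 0.1 FPKM in the other groups. Among them MAL, a membrane protein of lymphocytes and myelin, was at 9.10 ± 2.70 FPKM (SD, n = 3) on 625 fragments and was listed at 0 in control.

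Markers of other cell types were low apart from a few genes. The desmosome gene DSP made up most of the keratinocyte list and was at 21.5 ± 0.754 FPKM in control, 88.4 ± 2.37 FPKM after 4 h and 76.1 ± 1.73 FPKM after 24 h of calcipotriol, while the summed list was at 28.9 ± 0.191, 98.4 ± 2.37 and 83.6 ± 0.395 FPKM. With chaetocin the stratifin gene SFN rose to 5.84 ± 0.443 against 0.0311 ± 0.0538 FPKM. Melanocyte markers summed with chaetocin to 8.95 ± 0.803 against 0.654 ± 0.0869 FPKM in control, PMEL among them at 4.01 ± 0.629 against 0.103 ± 0.0112 FPKM, and the endothelial receptor KDR was at 1.83 ± 0.187 against 0.0810 ± 0.0229 FPKM. A mean of at least 1 FPKM was reached by 0 melanocyte, 1 endothelial and 2 keratinocyte markers in control and by 4, 5 and 5 with chaetocin, so numbers of higher members would follow from the filter and are not given. The macrophage gene CD68 held most of the leukocyte sum and rose with VDR siRNA to 56.6 ± 2.73 against 34.4 ± 1.61 FPKM. Of the germline genes, TEX101 was at 5.94 ± 0.867 FPKM with chaetocin and listed at 0 in control.

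Mitosis genes were higher than control in all 4 treated groups. Library scaling as the cause is argued against by the lowest median over 4 comparisons and 5 scalings, which was 1.99 on the log2 scale. Few dividing cells in the control cultures alone is a candidate explanation for both calcipotriol groups and VDR siRNA, whose medians differed by at most 0.422. Whether it is the whole cause with chaetocin stays open. The 4 medians against control differed by 1.11 (1.06 to 1.71 over 18 other settings). Chaetocin's median was 0.91 and 0.68 above those of 24 h of calcipotriol and VDR siRNA. Tested directly against these groups, the list had medians of 0.72 and 0.60 with chaetocin (camera adjusted p = 0.000345 and 0.00146). With an estimated correlation, camera gave adjusted p = 0.356 and 0.430. After 4 h of calcipotriol the list's median was already 2.17, against 2.37 after 24 h. The labels give no cell density. An effect of each treatment on division stays open, and these data cannot tell it from the state of the control cultures.

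Chaetocin libraries had more genes with fragments than the other 12. Depth is argued against, since with all libraries thinned to 15 M fragments the lowest chaetocin library had 11945 more genes than the highest other library. Genomic DNA at a single rate would give 3033 nearly silent genes similar fragments per kb, but the 90th percentile was 27.7 and the 10th was 0, so that their ratio has no value, with 11.2% of these genes without a fragment against 0.00192% at a single rate. Olfactory receptor genes, 141 of 381 with a fragment, bound such a rate to one that could give 4104 of the 12827 extra genes, so part of the rise stays open. Unspliced RNA of neighbours that were expressed in control and lay within 10 kb is argued against as the whole cause. Of the 613 genes, 67.7% lay over 10 kb from every gene expressed in control. The share was 74.1% of 6154 genes with a fragment in each chaetocin library and none in control. But 32.3% and 25.9% lay within 10 kb. The share was 14.45% of 2000 genes drawn from those under 0.1 FPKM in the other groups and on average with chaetocin. It was 14.97% of genes without a fragment with chaetocin or in control. Unspliced RNA of neighbours thus stays open for a part. Neighbours expressed only with chaetocin, and RNA that ran farther than 10 kb, were not covered by this test and stay open. A loss of silencing stays open too and was not tested.

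Of the genes called with both, 24 h of calcipotriol and VDR siRNA moved most in the same direction, with 2875 shared against 462 opposite calls, while over all 15195 genes 68.8% had the same sign, against 66.7% simulated for unchanged groups. Chance values of the shared controls, at the spread seen between libraries of a group, are argued against by a covariance of 0.116, against 0.0157 simulated. That spread may be technical, so a chance shift of the control cultures as a whole is not covered. The state of the control cultures stays open. Of the shared genes, 73.9% had the same sign with 4 h of calcipotriol, 76.7% with chaetocin and 57.9% with both. The last share is most of them, the outcome set beforehand for this explanation. Simulated unchanged genes against shared controls gave 58.7% to 61.2%. Those were not called genes, so they give no value to set the 57.9% against, and the test cannot decide. A shared effect through VDR stays open and was not tested, and VDR was lower in all 4 treated groups, with log2 fold changes of -0.46 and -1.52 in these and -1.30 and -1.77 with 4 h of calcipotriol and chaetocin. CYP24A1 moved in opposite directions, with 8.17 for 24 h of calcipotriol and -0.47 for VDR siRNA.

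Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. As many genes as the real split came from 1 of the 10 splits each time. In the fit of all 15 libraries, with the 6 compared regrouped, the real splits gave 8609, 5062, 12026, 5714 and 8271 genes for 4 h and 24 h of calcipotriol, chaetocin, VDR siRNA and the 2 times, and the highest other split gave 1, 1, 1, 1 and 2. The other splits mix libraries of the 2 groups compared, so the difference between the groups enters their spread. Their low counts therefore do not measure how many calls are false.

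The libraries of a group were alike, and the first 4 principal components held 58.3%, 15.7%, 7.07% and 5.62% of the variance. Fragments differed between libraries of a group by more than counting error, with chi-square per degree of freedom of 4.63 to 7.84, so that no library was a copy of another.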
